A study of Mus musculus with 212 samples.

How the data were processed

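Gene expression was measured in mouse embryonic stem cells, the MC1R(20) line with a tetracycline-controlled cassette in the ROSA26 locus, in which withdrawal of doxycycline switches on a transgene. Each of 52 derived lines carried the open reading frame of 1 named protein, mostly a transcription factor, and 1 line was labelled Control. Per the labels, cells were plated with doxycycline at 0.2 ug/ml and puromycin at 1.5 ug/ml, rinsed after about 18 hours and given new medium at intervals of 3 hours, and RNA was taken 48 hours after the last wash, on day 2. By design, cells kept in doxycycline (Dox+) had the transgene off, and cells without it (Dox-) had the transgene on. Induction of the transgene was not checked in any line. Each line and condition had 2 arrays, which makes 106 groups and 212 arrays. The labels number the samples as cultures of one clone per line and do not say that the cultures were grown independently, so the p-values measure the spread between these samples, part of which may be technical.

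Each array was hybridised with the sample RNA in Cy3 and a common reference in Cy5, a mixture of a commercial universal mouse RNA and embryonic stem cell RNA, per the labels. Per the submitters' processing notes the tool was Agilent Feature Extraction, and its version and the normalisation after it are not given in the sources used here. The authors deposited one table of log10 values with 25030 probes and a column for each array; the unit is inferred from the values, as neither the labels nor the table names the logarithm. The values behave as the sample signal and not as a ratio to the reference: array medians lay between 2.23 and 2.30 and single values between -1.82 and 5.93. Direction is that of a signal, and whether and how the arrays were scaled to each other before deposit stays unknown. No value was missing and no array was a copy of another. The lowest correlation between 2 arrays was 0.953 and the highest was 0.996. The log10 values were divided by the log10 of 2, so that all changes below are log2 changes; if the deposited logarithm had another base, every fold would change with it, and the counts at a fold threshold as well. Flags for signal over background are not used here, so a change of a dim probe is a difference between values near the lower end of the scale and can understate the true change. The number of arrays limits the precision.

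The probes carry numbers only. The files do not pair these numbers with genes, and the gene table at hand has no column of array feature numbers and is not used here, so counts are counts of probes and not of genes. The planned check of each transgene's own probe, the planned tests of 27 gene lists, the planned relation of induction to response size and the planned averaging of several probes of a gene were therefore not run, and of the rule for naming genes, which took the largest changes per line and the most recurrent ones, the 2 probes that rose and the 2 that fell in the most lines are given.

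The change in each line was tested with limma 3.58.1 in R 4.3.3: one linear model with a mean for each of the 106 groups over all 212 arrays, the contrast Dox- minus Dox+ within the line and moderated variances (106 residual degrees of freedom and 1.31 prior degrees of freedom). A probe is called responding when its Benjamini-Hochberg adjusted p within the line was under 0.05 and its change was at least 1.5-fold. The spread is shared over all groups, so that a line with noisier arrays than the others is given too small an error. The mean response was tested with limma on the 52 differences of the factor lines, each line counting once, at an adjusted p under 0.05 and a mean change of at least 1.2-fold. The mean of the factor lines minus the Control line, and the difference between the responses in each of 18 pairs of related lines, were tested as contrasts of the first model at the thresholds for single lines. Pairs, thresholds and the alternatives, except those named below, were chosen before the data were examined. Similarity of 2 lines is the Pearson correlation of their log2 changes over all probes, ranked among the 1378 pairs of lines. The overlap of 2 independent lists was computed within 400 classes of probes, 20 of mean signal and within each 20 of spread between replicates, since both set how readily a probe is called, and the shuffles of calls within lines kept each call in its class. These classes were chosen after the data were seen. No expected number was computed for probes called in opposite directions. Probes are not independent replicates, so these correlations describe the lines and carry no p. No 2 lines share an array.

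On simulated values with the spread of the real probes, 200 probes per line among 25030 were changed. By the adjusted p alone, without the fold threshold, the test within lines found with the right sign 49.3% of probes changed 1.5-fold. It found 64.3% of those changed 2-fold and 85.2% of those changed 4-fold. Among the brightest 25% of probes it found, again by the adjusted p alone, 96.2% of the 1.5-fold changes, and among the dimmest 25% 6.04%. The shares found past both thresholds were not computed and can only be the same or lower. Of the calls of this test past both thresholds 3.03% fell on unchanged probes. The simulated noise was independent between arrays and alike in all groups, with no slide effect. Shares of false calls given here can therefore be too low for noisy lines and for lines on several slides. The test of the mean over lines found 94% of 200 probes changed 1.4-fold, with 2.59% of calls on unchanged probes, and the test of a difference between 2 lines found 76.4% of probes 4-fold apart, with 3.90% of calls on equal probes.

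The 212 arrays lay on 57 slides. All 4 arrays of 37 lines lay on 1 slide each, with Dox+ always at positions 1 and 2 and Dox- always at positions 3 and 4. In 16 lines, the Control line among them, the arrays were spread over more than 1 slide. Alternatives were quantile normalisation between arrays, leaving out the 25% of probes with the lowest mean, slide as a random block, the replicate number or the culture number as a block, each replicate left out in all lines at once, the 4 arrays of a line alone, only slides that hold both conditions, and for the mean response the difference in slide position as a covariate and each kind of slide layout alone. A variance that depends on the signal, crossed replicate numbers, 4 further choices on the mean response and the Control line, and the dim-probe filter and replicates left out for pairs were added after the data were seen. Among random sets of lines, resampling was done 100000 times.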

Results

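The series held two-colour microarrays of mouse embryonic stem cells, in which 52 lines each switched on 1 named protein when doxycycline was withdrawn. A line labelled Control took the same withdrawal. Every line had 2 Dox+ arrays and 2 Dox- arrays, taken 48 hours after the last wash. The title of the series poses the question of what the early responses to many transcription factors have in common. The comparisons were the response within each line, the background in the Control line, the difference between related factors, and the response averaged over lines. Probes carry no gene names in the files, so the lines are named by their factor and the responses are given as numbers of probes out of 25030.

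Cdx2, a homeobox factor that specifies trophectoderm, had the largest response, except in the fits with the culture number as a block and with the 4 arrays of each line alone. The first of these takes the change only from culture numbers shared by both conditions, 1 for Cdx2 and 2 for Esx1. It therefore does not compare these lines on equal numbers of arrays. In the Cdx2 line 3639 probes rose and 3538 fell, 28.7% of all probes. Its 7177 responding probes were 5873 in the first of these fits, where Esx1 had 6046, and 5609 in the other, where Sox9 had 5921. Esx1, a homeobox factor of placenta and germ cells, followed with 3291 higher and 2782 lower probes, Tcf3 with 3111 and 2876, and Sox9, a factor of cartilage and testis development, with 3252 and 2692. Klf4, a zinc finger factor used in reprogramming, had 3010 higher and 2212 lower probes, and Gata3, a zinc finger factor of trophoblast and T cells, had 2428 and 2292. The next 5 lines by size were Sox2, Dlx3, Eomes, Nrip1 and Ascl2, with 3745, 3699, 3696, 3431 and 3233 responding probes. These 11 lines passed 3000 responding probes, and the 10 largest lines held 55.3% of all 89865 calls. In the Cdx2 line the largest rise among responding probes whose arrays did not overlap was 7.54 ± 0.33 on the log2 scale (SE, n = 2 arrays per condition, adjusted p = 5.87e-41), and the largest fall was -6.79 ± 0.11 (SE, adjusted p = 8.29e-83). The Gata3 line had a largest rise of 7.76 ± 0.33 (SE, adjusted p = 8.58e-42). Of the 52 factor lines, 26 had at least 1000 responding probes, and the median was 1053. More probes rose than fell in 34 lines and more fell than rose in 18. The balance lay furthest toward lower probes in the Cbx8 line, which carries a Polycomb protein, with 87 higher and 241 lower. Tcea3, an elongation factor expressed in embryonic stem cells, had 1299 higher and 998 lower probes, but 65.3% of them lay among the dimmest 25% of probes, and quantile normalisation between arrays left 278 higher and 733 lower. Its count of 2297 was 863 without the second Dox- array and 1270 without the second Dox+ array.

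**Figure D1:**
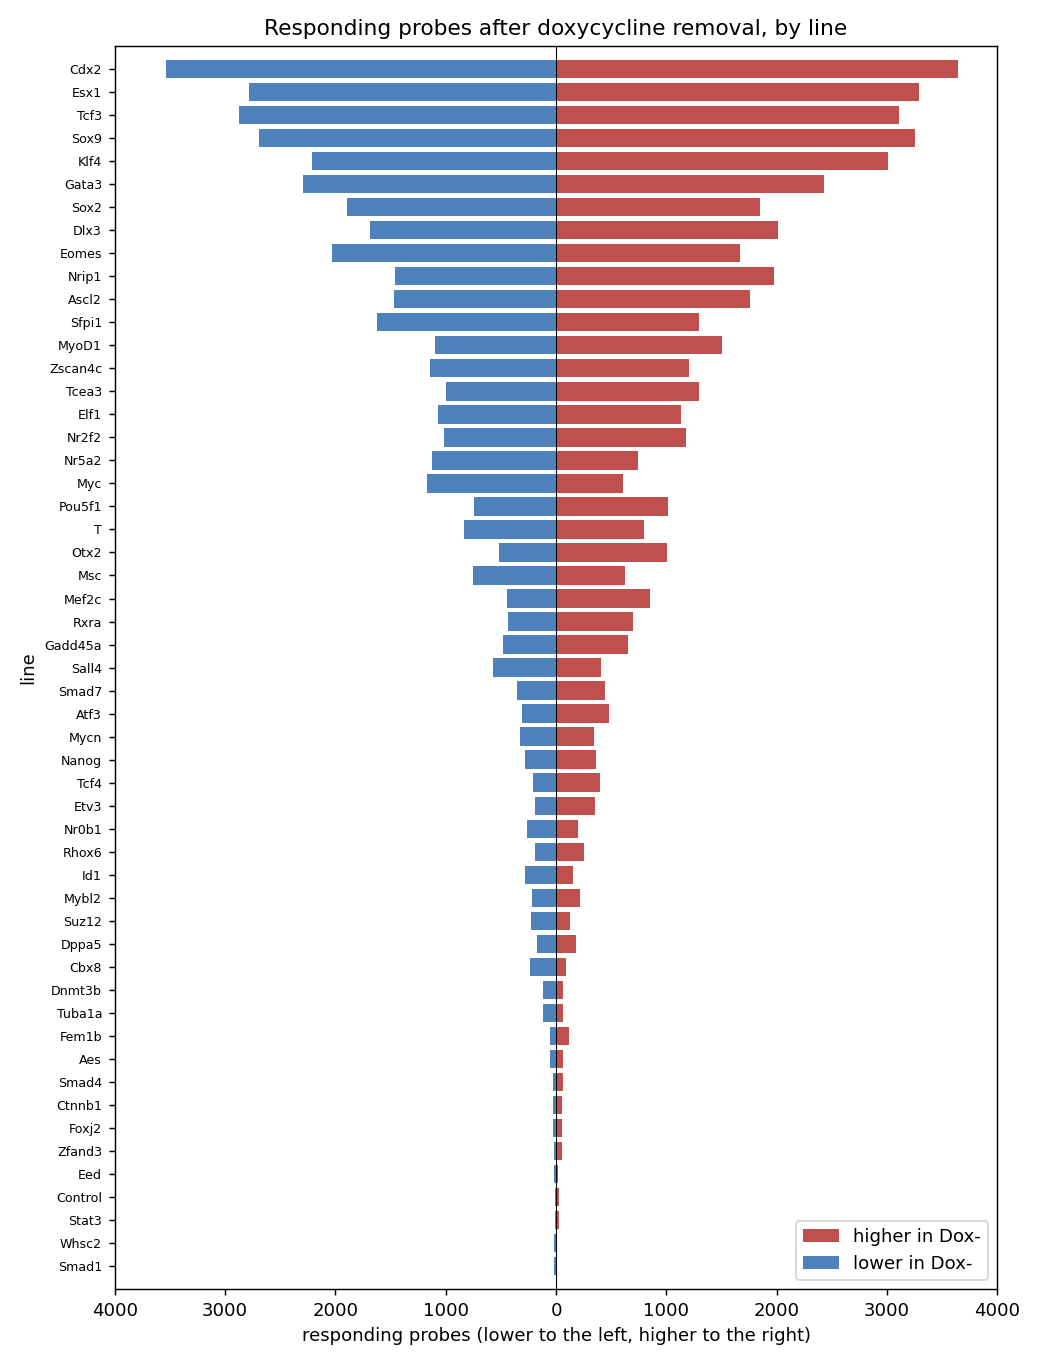
Bars give for each of the 53 lines the number of probes that rose (red, to the right) and fell (blue, to the left) after doxycycline removal, at an adjusted p under 0.05 and at least 1.5-fold, ordered by their sum. Cdx2 stands at the top with 3639 higher and 3538 lower probes, and the Control line, with 25 and 13, lies near the bottom.

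The Control line had 38 responding probes, 25 higher and 13 lower, measured in the same way. Of these, 9 of the higher and 8 of the lower probes passed the threshold in that direction in no factor line, and no slide held both conditions of Control. In 3 factor lines the count was lower, namely Stat3 with 34, Whsc2 with 28 and Smad1 with 24, and Eed, a Polycomb protein, had 39. Stat3 transmits the signal of leukaemia inhibitory factor, Whsc2 is a subunit of the elongation complex NELF, and Smad1 transmits bone morphogenetic protein signals. A further 4 factor lines stayed under 100 responding probes: Smad4 with 96, Ctnnb1 with 77, Foxj2 with 77 and Zfand3 with 72. Single arrays moved these small counts. Smad4 had 731 responding probes without the second Dox- array, Zfand3 523 and Eed 89 without the first Dox+ array, Whsc2 241, Ctnnb1 200 and Stat3 101 without the second Dox+ array, and Smad1 185 without the first Dox- array. The lowest counts were 8 in Smad1, 14 in Eed, 15 in Whsc2 and 42 in Ctnnb1 without the second Dox- array, 26 in Smad4 without the first, 36 in Foxj2 without the first Dox+ array and 26 in Zfand3 without the second. Between 20.8% (Smad1) and 84.4% (Ctnnb1) of the calls in these 9 lines lay among the dimmest 25% of probes. The Control count was 112 without its second Dox- array and 16 with slide as a random block, and its arrays lay on 3 slides.

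Among the factors of the pluripotent state, Sox2 had 1850 higher and 1895 lower probes, Pou5f1 had 1015 and 744, and Nanog had 361 and 281. Sox2 and Pou5f1 bind DNA together in embryonic stem cells. Their responses differed at 3568 probes, with a correlation of 0.09 at percentile 73.1 of all pairs of lines. They shared 233 higher probes, where independent lists of probes of like signal and spread would share 114, and 231 lower probes, where 90.4 would be shared. At 291 probes they responded in opposite directions. Pou5f1 and Nanog differed at 2184 probes, with a correlation of -0.03, which was 0.06 without the second Dox+ arrays. They shared 40 higher and 18 lower probes against 29.2 and 11.9 and had 115 in opposite directions. Nanog and Sox2 differed at 3846 probes, with a correlation of -0.02, which was 0.08 without the second Dox+ arrays. They shared 62 higher and 57 lower probes against 42.7 and 30.5 and had 185 in opposite directions. In the pairs of Nanog with Pou5f1 and with Sox2, opposite calls outnumbered the sum of shared higher and shared lower probes. For Sox2 and Pou5f1 that sum was larger than the number of opposite calls. No expected number was computed for opposite calls, so the balance of shared and opposite calls could not be compared with that of independent lists. This balance therefore does not show a tendency of these responses to go together or apart. The Nanog count was 1342 without the first Dox+ array. Klf4 and Nr5a2, an orphan nuclear receptor that can replace Pou5f1 in reprogramming, differed at 6548 probes, or 5338 with slide as a random block, and 631 probes responded in opposite directions. They also shared 168 higher probes against 125 and 130 lower probes against 127. Their correlation of -0.16 was at percentile 0.508. The Dox- arrays lay on earlier slides than the Dox+ arrays in the Klf4 line and on later slides in the Nr5a2 line. Nr5a2 and Nr0b1, an atypical nuclear receptor that binds Nr5a2, correlated at 0.25 and differed at 962 probes. The correlation was 0.17 with slide as a random block and 0.07 without the first Dox+ arrays. They shared 45 higher and 64 lower probes against 9.49 and 16.9 and had 13 in opposite directions. The first Dox+ array of Nr0b1 lay on an earlier slide than its other arrays, so in both lines the Dox- arrays lay more on later slides. A shared response of Nr5a2 and Nr0b1 can therefore not be told apart from a difference between slides. No slide held both conditions of Nr5a2, so a value within slides cannot be had for this pair or for Klf4.

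Among the factors of trophoblast and mesoderm, Cdx2 and Gata3 had 1038 probes that rose in both lines, where independent lists of like probes would share 449, and 1165 that fell in both, where 448 would be shared. At 488 probes they responded in opposite directions. Their correlation was 0.33, at percentile 98.4 of pairs. Cdx2 and Dlx3, a homeobox factor of the placenta, shared 924 higher and 862 lower probes against 375 and 321, with 376 in opposite directions and a correlation of 0.36. Cdx2 and Eomes, a T-box factor of trophoblast and mesoderm, shared 762 higher and 1018 lower probes against 323 and 413, with 388 in opposite directions and a correlation of 0.34. The tests of the difference called 5836 probes between Cdx2 and Gata3, 5748 between Cdx2 and Dlx3 and 5961 between Cdx2 and Eomes. T and Eomes, both T-box factors, shared 334 higher and 542 lower probes against 81.2 and 117, with 99 in opposite directions, correlated at 0.33 and differed at 2710 probes. The highest correlation over all pairs of lines was 0.59, between Esx1 and Tcf3, followed by 0.53 between Sox9 and Tcf3, while the median over pairs was 0.04.

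MyoD1, the basic helix-loop-helix factor that specifies skeletal muscle, and Ascl2, a basic helix-loop-helix factor of trophoblast and intestinal stem cells, had the highest correlation of the 18 pairs fixed in advance, 0.46, the third highest of all 1378. In the 2 lines 826 probes rose together, where independent lists of like probes would share 167, and 546 fell together, where 96.2 would be shared. At 53 probes they responded in opposite directions. Still, 1502 probes differed between them, 776 higher in the MyoD1 line and 726 lower. Mef2c, a partner of MyoD1 in muscle, correlated with it at 0.23, shared 308 higher and 134 lower probes against 78.9 and 34.8, with 121 in opposite directions, and differed at 2313.

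Myc and Mycn, which bind the same E-box sequence, shared 89 higher and 83 lower probes against 12.1 and 19.9, with 7 in opposite directions, and differed at 1055 probes. Their correlation of 0.20 was 0.09 without the first Dox- arrays. In the Myc line 1168 probes fell and 603 rose, and in the Mycn line 330 fell and 340 rose. The Mycn count of 670 was 1545 without the first Dox- array, which shared a slide with the Dox+ arrays, 314 without the second, and 441 with slide as a random block. The difference from Myc moved with it, to 1945 and 572. Tcf3 and Tcf4 differed at 5004 probes, as Tcf4 had 398 higher and 211 lower probes, and correlated at 0.18, or 0.11 without the first Dox- arrays. They shared 159 higher and 111 lower probes against 75.4 and 39.5 and had 92 in opposite directions. Of the Smad proteins, Smad7, an inhibitor of the pathway, had 445 higher and 353 lower probes and differed from Smad1 at 612. Smad1 and Smad4 differed at 16, and at 149 without the second Dox- arrays. Of the Polycomb proteins, Eed differed from Suz12 at 182 probes and from Cbx8 at 172. The first Dox- array of Suz12 lay on another slide than the other 3. Its count of 354 was 56 without that array and 2192 without the second, and the difference from Eed was 33 and 1912. Sfpi1, the myeloid factor PU.1, and Elf1, both of the ETS family, shared 240 higher and 324 lower probes against 89.0 and 119, with 207 in opposite directions, correlated at 0.19 and differed at 2941.

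Averaged over the 52 factor lines, 787 probes were higher and 638 lower in Dox- cells, with a median change of 0.38 and -0.37 on the log2 scale. Of these, 258 higher and 136 lower probes had the same sign in at least 75% of the lines. Without the 10 largest lines, 305 probes were higher and 274 lower, of which 256 and 187 were among those of all lines. In the Control line the median change was 0.01 over the higher and 0.07 over the lower probes. Among single calls, 848 probes rose in at least 10 factor lines and 825 fell in at least 10, where the highest of 100 shuffles within lines, each among probes of like signal and spread, was 24 and 27. In the 15 factor lines spread over several slides alone, 4 probes were higher and 1 lower. With the difference in slide position as a covariate 293 were higher and 490 lower, as estimated for a line with no such difference. All 37 lines on 1 slide had the same difference in position, so it could differ only in the spread lines. The covariate therefore cannot separate position from the spread over slides.

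Probe 5084 rose in 51 of the 52 factor lines, by 3.23 ± 0.14 on the log2 scale over all lines (SE, n = 52, adjusted p = 3.78e-25). It rose by 2.87 ± 0.42 in the Control line as well (SE, adjusted p = 1.03e-05). The exception was the line of Nrip1, a corepressor of nuclear receptors, with -0.16 ± 0.42. Probe 11846 rose in 43 factor lines, by 1.42 ± 0.08 (SE, n = 52, adjusted p = 1.69e-19), and by 1.94 ± 0.30 in Control. Probe 10751 fell in 24 factor lines and rose in 2, with a mean of -0.86 ± 0.19 (SE, n = 52, adjusted p = 0.00173) and a lowest value of -5.98 in the Cdx2 line. Probe 26131 fell in 23 and rose in 3, with a mean of -0.90 ± 0.16 (SE, n = 52, adjusted p = 0.000251) and a lowest value of -3.67 in the Ascl2 line. Neither of these passed the threshold in Control, where they changed by -0.19 ± 0.26 and 0.18 ± 0.13.

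**Figure D2:**
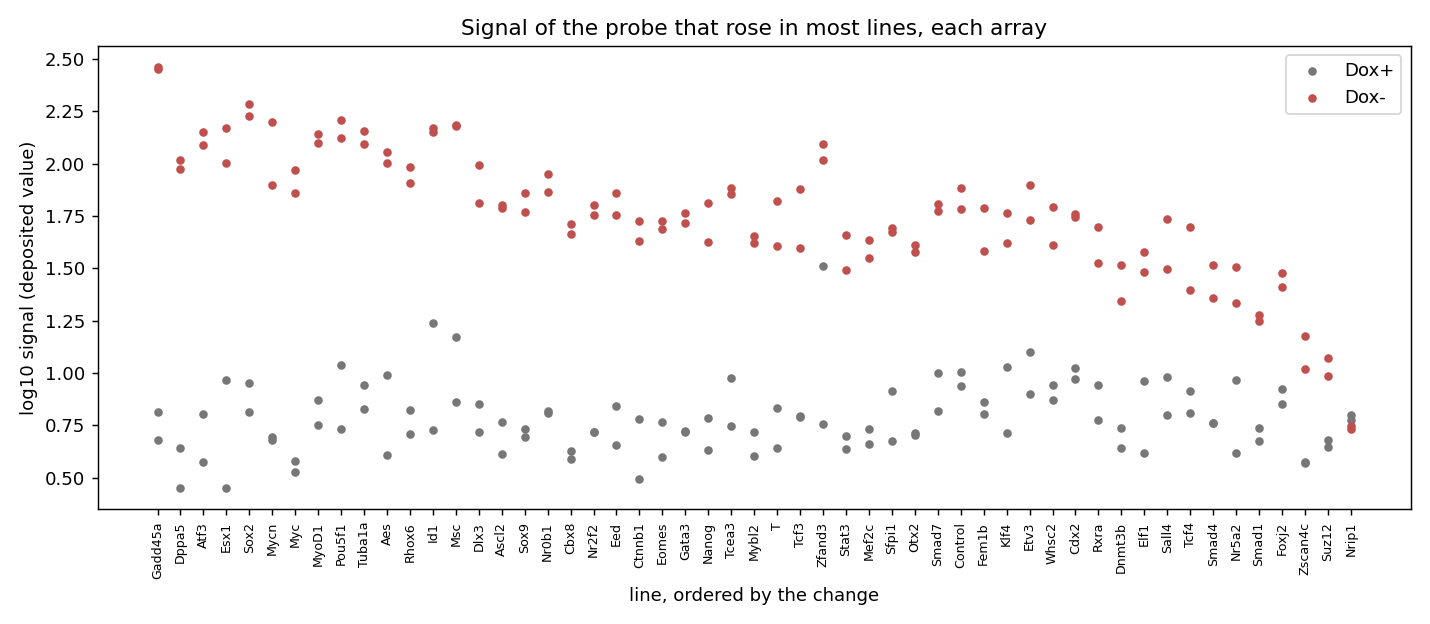
Each point is 1 array, with the deposited log10 signal of probe 5084 on the vertical axis and the 53 lines on the horizontal axis, ordered by their change; grey marks Dox+ and red Dox-. The Dox- arrays lie above the Dox+ arrays of their line except in Nrip1 at the right end, where all 4 arrays lie between 0.73 and 0.80.

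Set against the Control line, the mean over the factor lines was higher at 87 probes and lower at 185. Of these, 49 and 80 were also in the mean response. This comparison rests on the 4 Control arrays. The first Dox- array of Control lay on an earlier slide and its other arrays on later slides, and no slide held both conditions. Its Dox- arrays also sat at lower positions than its Dox+ arrays (mean difference -1.5), the reverse of the 37 lines on 1 slide. The contrast therefore cannot separate an effect of the factors from one of slide or position in the Control line. With slide as a random block it called 51 and 94 probes, without the second Dox- arrays 138 and 431, and without the first Dox+ arrays 96 and 92, where lower probes were no longer the more numerous. With the later Control arrays alone it called 75 and 117.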

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

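The tests of the Control change, of the Nrip1 labels, of all 13 lines with more later slides in Dox- and of their later against earlier Dox- arrays were chosen after the results were seen; the pairs of lines, the position test, the relation over the 16 spread lines and the regression among 5 lines were set before their results were seen. All 18 pairs of related lines responded differently at some probes by the test of the difference itself. The numbers of differing probes were 6548 for Klf4 and Nr5a2, 5961 for Cdx2 and Eomes, 5836 for Cdx2 and Gata3, 5748 for Cdx2 and Dlx3, 5004 for Tcf3 and Tcf4, 3846 for Nanog and Sox2, 3568 for Pou5f1 and Sox2, 2941 for Sfpi1 and Elf1, 2710 for T and Eomes, 2313 for MyoD1 and Mef2c, 2184 for Pou5f1 and Nanog, 1502 for MyoD1 and Ascl2, 1055 for Myc and Mycn, 962 for Nr5a2 and Nr0b1, 612 for Smad1 and Smad7, 182 for Eed and Suz12, 172 for Eed and Cbx8 and 16 for Smad1 and Smad4.

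The Nrip1 line differed from the mean of the other 51 factor lines at probe 5084 by -3.46 ± 0.42 on the log2 scale (SE, adjusted p = 8.39e-12). Position on the slide is argued against as the source of the common rise, since the probe rose in all 7 lines whose Dox- arrays sat at the same or lower positions than their Dox+ arrays. Induction of a factor is argued against as its source by the Control line, whose change was 88.9% of the mean over the factor lines. The Dox+ signal of the probe was dim, with a mean log10 of 0.78 at percentile 13.8 of probes, so this percentage is imprecise. Swapped or uninduced Nrip1 arrays are argued against by the line's responding probes, 90.3 times those of Control, with no fall of the probe. What stays open is that the probe may read a sequence of the shared vector or a direct response to doxycycline, with the Nrip1 clone an exception; the files give no probe sequence to test this.

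In 13 lines more Dox- than Dox+ arrays lay on the last 11 slides in barcode order, and their 78 pairs correlated from -0.09 to 0.52 with a median of 0.11 outside the dimmest 25% of probes, against 0.05 among the other lines and 0.03 after the difference between later and earlier replicates of one condition in other lines, estimated from 12 pairs of arrays, was regressed out. A difference between slide sets is a candidate explanation. Over the 16 spread lines, the correlation of a line's response with the difference between later and earlier replicates rose with the excess of later slides among its Dox- arrays. Pearson r was 0.806 (permutation p = 0.00047) and Spearman rho 0.784 (permutation p = 0.00016), both two-sided. Without the 2 lines farthest from the median, r was 0.760. Most lines had the same excess, 0.5, and spread at it from 0.10 in Sfpi1 and Cdx2 to 0.41 in Mycn. The relation therefore rests on the few lines with another excess. Msc and Nr5a2, at 1, had 0.44 and 0.40. Klf4 at -1 had -0.21, Control at -0.5 had -0.26, and Whsc2 at 0 had the lowest value, -0.37, against the order. The first Dox+ array of Whsc2 lay on the slide just before the last 11. If that slide belongs to the later set, the excess of Whsc2 is negative, as in Klf4 and Control. The place of Whsc2 in the order thus depends on where the set was cut, and another cut was not tested. In Mycn, Suz12 and Rhox6, which each had a Dox- array on the slide of their Dox+ arrays and another on 1 later slide, the mean correlation was 0.41 with the later Dox- arrays and -0.06 with the earlier ones (exact one-sided p = 0.125, the smallest that 8 choices of arrays can give). A shared response of some of these factors stays open: among Msc, Mybl2, Nr5a2, Nr0b1 and Tuba1a, picked because they resembled each other, the median correlation was 0.32 and 68.4% of it was left after the regression, but a noisy estimate removes too little. For Mybl2 and Nr0b1, which have a slide that holds both conditions, the correlation was 0.30 over all arrays and 0.16 within slides. The value within slides used only 2 arrays of Mybl2 and 3 of Nr0b1. Fewer arrays alone can lower a correlation, so the drop does not show an effect of slides.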

How the results depend on the processing

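All tests with a signal-dependent variance, with crossed numbers, without Tcea3 or the 10 largest lines, with the later Control arrays alone, of the mean response with slide as a random block, and of pairs without dim probes or without a replicate were chosen after the data were seen. The signal-dependent variance moved no count by over 1.5 times and shared 99.7% of the calls. Of the 53 counts per line, quantile normalisation kept 51 within 1.5 times, slide as a random block 48, the culture number 44 and the filter on dim probes 42. Quantile normalisation took Tcea3 to 1011 and Ctnnb1 to 48. It also moved the split of higher and lower probes by over 10 points in Ctnnb1 (18 and 30, against 53 and 24), Msc (751 and 603, against 626 and 751), Mybl2 (276 and 169, against 214 and 217), Nr5a2 (924 and 928, against 740 and 1122), Stat3 (26 and 17, against 25 and 9), Tcea3 (278 and 733, against 1299 and 998) and Zfand3 (48 and 48, against 50 and 22). The median over all probes moved by at most 0.07 in any line. Slide as a random block, with an estimated correlation of 0.309, gave Msc 832, Mycn 441, Tuba1a 104, Suz12 67 and Control 16. Within slides that hold both conditions, which 10 of the 16 spread lines have, Mybl2 had 239, Mycn 330 and Suz12 97, and the other 7 stayed within 1.5 times; Control, Elf1, Klf4, Msc, Nr5a2 and Tuba1a have no such slide and gave no value. Without the dimmest 25%, which by construction leaves out their dim calls, Tcea3 had 730, Dppa5 112, Dnmt3b 86, Tuba1a 86, Foxj2 50, Smad4 22, Stat3 20, Eed 18, Control 16, Whsc2 16 and Ctnnb1 14. The 4 arrays of a line alone leave 2 degrees of freedom; limma then called 0 probes in 29 lines, where between 547 and 3193 passed an unadjusted p of 0.05 and the fold, and Ascl2 2120, Nr5a2 1205, T 1033, Pou5f1 992, Mef2c 765, Myc 727, Smad7 444, Elf1 423 and Rxra 242. Apart from these the cause of a move was not tested.

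The labels hold a replicate number and a culture number, and arrays of both conditions with the same culture number carried different replicate numbers in 12 lines. Between conditions, 23 lines shared 1 culture number and 30 shared both. With the culture number as a block, the change in those 23 lines is taken from 1 Dox+ and 1 Dox- array. Neither numbering showed a clear pairing of the samples. The deviations of Dox+ and Dox- arrays with the same replicate number correlated between -0.18 and 0.20 over lines, with a median of 0.00 and 4 of 53 lines over 0.1. Those with the same culture number correlated between -0.20 and 0.16, with 3 over 0.1. In the 23 lines that shared 1 culture number, the latter values also rest on arrays whose number was not shared. Weak correlations do not show that the samples were unpaired. With the replicate number as a block the Cdx2 line had 7164 responding probes and Control 37, all 53 counts and the 18 pair differences stayed within 1.5 times, and 97.9% of the calls were shared. With the numbers crossed in the 3 lines under -0.1, Control had 43, Stat3 37 and Ctnnb1 83. With the culture number as a block Nanog had 1032, Zfand3 265, Aes 69, Smad4 63, Dnmt3b 61, Eed 22, Control 21, Whsc2 17 and Smad1 12.

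Leaving out 1 array of a condition assumes that the lone array varies like the other groups. The counts then ranged from 8 to 185 in Smad1, 14 to 89 in Eed, 15 to 241 in Whsc2, 24 to 101 in Stat3, 26 to 523 in Zfand3, 26 to 731 in Smad4, 33 to 112 in Control, 36 to 87 in Foxj2, 42 to 200 in Ctnnb1, 55 to 1079 in Tuba1a, 56 to 2192 in Suz12, 81 to 1158 in Dppa5, 82 to 308 in Dnmt3b, 101 to 188 in Fem1b, 229 to 952 in Mybl2, 291 to 964 in Rhox6, 314 to 1545 in Mycn, 341 to 656 in Etv3, 364 to 700 in Id1, 509 to 1342 in Nanog and 863 to 3022 in Tcea3. In the other 32 lines, all 14 of those with the most responding probes among them, the counts stayed within 1.5 times. Pair differences ranged from 33 to 1912 for Eed and Suz12, 572 to 1945 for Myc and Mycn and 20 to 149 for Smad1 and Smad4; Eed and Suz12 also fell to 26 with slide as a random block. The factor lines against Control ranged from 74 to 138 higher and 92 to 431 lower probes, and without the first Dox+ arrays, at 96 and 92, the excess of lower probes was lost, with 51 and 94 under slide as a random block and 117 lower with the later Control arrays alone. The mean response had 305 higher and 274 lower probes without the 10 largest lines, 293 higher with the position covariate, and 4 higher and 1 lower in the 15 spread factor lines alone, where fewer lines enter; under the other settings tried both counts stayed within 1.5 times. Correlations ranged over settings from 0.07 to 0.32 for Nr5a2 and Nr0b1, 0.09 to 0.29 for Myc and Mycn, 0.11 to 0.21 for Tcf3 and Tcf4, -0.07 to 0.06 for Pou5f1 and Nanog and -0.05 to 0.08 for Nanog and Sox2. That of MyoD1 and Ascl2 ranged from 0.33 to 0.57. The own-gene, gene list, induction and several-probe alternatives were not run. Signal over background limits all counts, as by the adjusted p alone 6.04% of simulated 1.5-fold changes were found in the dimmest 25% of probes.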

Other observations

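The tests of the line families and of the Tcea3 probes outside the dimmest 25% were chosen after the results were seen. The lines tied to trophoblast by the gene lists fixed in advance were Cdx2, Gata3, Eomes, Ascl2, Esx1, Dlx3 and Rhox6. All their 21 pairs correlated above 0, from 0.07 to 0.43, with a mean of 0.25. Random sets of 7 factor lines matched coarsely on the size of the response had a mean of 0.13 (adjusted one-sided permutation p = 0.0150 over 5 families). This test cannot separate a family response from one common to lines with large responses. Esx1, Gata3, Eomes and Cdx2 also correlated with the mean of all other factor lines, at 0.50 to 0.61 outside the dimmest 25% of probes. Tcf3, outside this family, correlated with Esx1 at 0.59. The lines tied to the skeletal muscle list, MyoD1, Mef2c, Msc and again Ascl2, had a mean correlation of 0.19 against 0.08 in matched sets (adjusted one-sided permutation p = 0.0297), with 6 pairs from -0.03 to 0.46. The highest was MyoD1 and Ascl2, and the other 5 had a mean of 0.14. Without Ascl2 the mean was 0.11 against 0.06 in matched sets for muscle (adjusted one-sided permutation p = 0.133 over 2 sets), so that this result rests on Ascl2, and 0.26 against 0.12 for trophoblast (adjusted one-sided permutation p = 0.00254). The labels do not say which of the proteins known as Tcf3 and Tcf4 were induced, and they are taken here as Wnt factors. The means of the Wnt lines (Ctnnb1, Tcf3, Tcf4 and Aes), the Smad lines with Id1, and the Polycomb lines with Cdx2 were 0.05, 0.01 and 0.02, which did not stand out from matched sets (adjusted one-sided permutation p = 0.612, 0.835 and 0.742); these p-values do not show that the families lack a shared response. Several of these lines had few responding probes.

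The lines closest to the mean response of all other factor lines were Esx1 (0.61), Tcf3 (0.55), Gata3 (0.54), Eomes (0.53) and Cdx2 (0.50), over probes outside the dimmest 25%, while Pou5f1, with 1759 responding probes, correlated with that mean at 0.02. The lines with the most probes that responded in no other factor line were Tcea3 with 764, Cdx2 with 736, Esx1 with 379 and Sox9 with 378. Of all responding probes of Tcea3, 65.3% lay in the dimmest 25%, and its 764 were 396 without the second Dox- array and 157 without the second Dox+ array. Of all probes, 6055 responded in no factor line and 5182 in exactly 1. The probe 5084 had a log10 signal of 1.51 on the second Dox+ array of Zfand3 against 0.76 on the first, and that line had 26 responding probes without the second Dox+ array and 523 without the first. Probe 11846 changed by 0.09 ± 0.30 in Nrip1 (SE). This was not particular to Nrip1, as the probe was not called in 9 factor lines and changed by 0.01 ± 0.30 in Suz12 (SE), where probe 5084 rose. The mean response called 1425 probes, and 1 of 100 assignments of signs to the lines, the real one, gave as many. The highest of the others gave 1 probe, so random signs of the lines did not give a response of this size. Random signs also cancel an effect of the slide layout that lines share. The test therefore cannot tell a common response from such an effect. Counts of the mean response were lower with the position covariate and in the spread lines alone, where fewer lines enter.

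Of the 2297 responding probes of Tcea3, 1500 lay in the dimmest 25%, 1113 of them higher. The shape of the dim end of the arrays is a candidate explanation for these, as 14.9% of them were left after quantile normalisation between arrays. For the 797 calls outside that part, 611 of them lower, a response of the cells stays open: they were 46.9 times those of Control there, and 714 were also called with the same sign after quantile normalisation. Single arrays moved them, to 328 without the second Dox- array, where Control had 70, 166 without the second Dox+ array and 1315 without the first.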
